A study of Homo sapiens with 6 samples.

How the data were processed

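Total RNA from 6 samples of NCI-H292 cells, 3 labelled DMSO and 3 labelled mitoxantrone (50 nM), was sequenced after 48 hours of treatment as paired reads of 150 bases, per the labels' protocols. RNA was enriched by poly(A) selection or by removal of ribosomal RNA; the labels name both kits and not which was used, nor whether libraries kept the strand. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1, Cufflinks 2.2.1 and DESeq2 without a version, with no role or order. The genome build and annotation are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical genes may have been dropped or divided.

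The authors' table is the 1 file used. It holds, per the file headers, raw read counts per gene and library and FPKM values per gene and library, as deposited by the authors. It also holds the mean normalized count over all libraries, a signal value from the authors' DESeq2 scaling, the authors' log2 fold change with its standard error, the Wald score of the authors' test and the authors' p-value and adjusted p-value. The table held 1305 genes, 793 higher and 512 lower. The smallest absolute log2 fold change was 1.0 and the largest adjusted p 0.043, so it is a list of genes selected on these libraries. The ratio of adjusted to raw p-values showed that the authors had tested about 18305 genes (18289 to 18321), of which about 4965 had an adjusted p at most that of the last listed gene; most of these were left out by the fold threshold. Genes left out were not analysed here, dispersions estimated from genes selected in this way tend to be too low and their folds too large.

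The 6 size factors (1.164, 0.971 and 1.167 for DMSO; 0.884, 0.96 and 0.932 for mitoxantrone) were solved from the deposited read counts and mean normalized counts, which they gave back with a largest relative error of 5.0e-10. The library totals were solved from FPKM, counts and gene lengths and gave back 100% of FPKM values within 0.006 or 0.02 percent. They ranged from 14762576 to 17817811 reads, of which the listed genes took 3.97% to 4.04% with DMSO and 6.08% to 6.2% with mitoxantrone. At these depths a listed gene had a median of 64.2 normalized reads. Intervals and floors (95%, 3 reads) cover counting error only. No 2 libraries of a group were duplicates: chi-square per gene between replicates was 2.74 to 28.01. Columns of per-library values used in no step numbered 0.

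Read counts were tested with the edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) for treatment alone, with the authors' size factors, no filter and a threshold of adjusted p 0.05. Benjamini-Hochberg adjustment used 18305 tests, a number set after the table had been seen to be a selection and before any fit. Ranks were taken among the 1305 listed genes only. Adjusted p-values are therefore at least as large as a ranking of all tested genes would give, and calls near 0.05 may be lost by this alone. Standard errors of log2 fold changes are the fold change divided by the root of the F statistic. On simulated data with the real genes' means, depths and fitted dispersions and 200 changed genes among 1305, the test recovered 56% of genes at a log2 fold of 1 and 90% at 2, with 0 of 1105 unchanged genes called. The simulated genes were mostly unchanged, while all real ones were selected as changed, and adjusting 1305 genes for 18305 tests makes calls harder. The 0 therefore does not measure the error rate of the real calls. The list test called 3.5% of random lists of 12 genes at an unadjusted p of 0.05. Random lists are the case for which the exact test is built, so a low rate was bound to follow. It does not measure the error for the real lists, whose members may change together.

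Before the data were examined, 31 gene lists, 25 single genes, the tests, the alternatives and the rule for named genes were fixed. Because the table holds selected genes only, each list with at least 5 listed members (17 lists) was tested for direction, higher against lower, against the other listed genes with a two-sided Fisher's exact test in scipy 1.17.1 and Benjamini-Hochberg adjustment in statsmodels 0.14.6. List medians were placed among 10000 random sets of listed genes matched on mean expression in 10 bins. Listed genes all lie past the authors' fold threshold. A list whose members share a direction is therefore pushed towards an end of these sets, whatever its size of change. The rule named the listed genes among the 25; the 10 largest rises and 10 largest falls among protein-coding genes past adjusted p 0.05 with a mean of at least 64.2, the median of the listed genes, and no overlap between the groups; and for each list with at least 5 listed members the 2 largest rises and 2 largest falls under the same conditions without that minimum. It named 78 genes, and list members named beyond it were chosen after their values were seen. Some genes that the rule named are not reported here. Gene types and GRCh38 coordinates came from GENCODE 29 by gene identifier, for 1267 of 1305 genes, of which 1048 were protein-coding; 38 had no match. The table's own coordinates belong to a build that is not named and served only to find neighbouring genes. Current symbols were found for 1259 identifiers and differed from the listed ones for 208.

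The alternatives were a threshold of adjusted p 0.001 or an absolute log2 fold change of 2, filters on low counts, protein-coding genes only, TMM or DESeq2 size factors over the listed genes, the DESeq2 Wald test (DESeq2 1.42.0), leaving out each library, the label number as a block, other backgrounds for the lists and the mean in place of the median. Alternatives added after seeing the data were Benjamini-Hochberg adjustment over the listed genes alone, scaling by total reads, removal of each library's trend with gene length, and the lists without each library. Gene Ontology terms given in the table and neighbouring genes were also examined after seeing the data. Scripts ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.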

Results

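Gene expression was measured by RNA sequencing in NCI-H292 cells, an established human lung cancer line, after 48 hours with 50 nM mitoxantrone or with the solvent DMSO at a 1 in 1000 dilution. Mitoxantrone is a cytotoxic drug that traps type II topoisomerase on DNA and causes DNA breaks. The series title places the comparison in a study of drug-induced senescence, a lasting arrest of cell division, and of therapy directed at LUNX. There were 3 libraries per treatment. The libraries held 17597475, 15789296 and 17817811 assigned reads with DMSO and 14762576, 15663223 and 14831147 with mitoxantrone, as computed from the deposited FPKM values. The deposited table held 1305 genes, all with an absolute log2 fold change of at least 1.0 in the authors' deposited table, so every count below describes genes that the authors had already selected as changed. Genes outside that table, among them 11 of the 25 genes fixed in advance (BPIFA1, which encodes LUNX, is one), were not analysed here. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

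Which transcripts mitoxantrone changed was the single comparison of the design. Among the listed genes, p53 targets, factors of the senescence-associated secretory phenotype, and growth factor and MAP kinase feedback genes were mostly higher with mitoxantrone. Genes of DNA replication, mitosis, and glutathione and xenobiotic metabolism were lower. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 3200 ± 329 (SD, n = 3) normalized reads with DMSO to 18794 ± 506 (SD, n = 3) with mitoxantrone. STC1, which encodes the secreted glycoprotein stanniocalcin 1, rose from 85.4 ± 27.2 (SD, n = 3) to 2089 ± 219 (SD, n = 3). TOP2A, which encodes the topoisomerase IIα that mitoxantrone traps, fell from 8105 ± 1285 (SD, n = 3) to 3903 ± 209 (SD, n = 3), and LMNB1, which encodes the nuclear lamina protein lamin B1, had a log2 fold change of -1.55 with a standard error of 0.13. The authors' deposited table gave 793 genes as higher and 512 as lower. With the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment for 18305 tests, 740 of these passed an adjusted p of 0.05 as higher and 461 as lower. Ranks were taken among the listed genes only, which enlarges the adjusted p-values and may leave out calls. The remaining 104 were weakly expressed, with a median of 7.88 normalized reads against 79.1 for the genes that passed. The 2 groups of libraries did not overlap for 1287 of the 1305 genes (98.6%, where chance gives 10% for 3 against 3), which the selection of the table favours. Higher genes made up 61.6% of the calls. Size factors computed over the listed genes alone, which treat most of them as unchanged, shifted the median log2 fold change by -0.66 (TMM) or -0.99 (DESeq2) and gave 398 higher against 512 lower (43.7% higher) and 219 against 512 (30%).

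**Figure D1:**
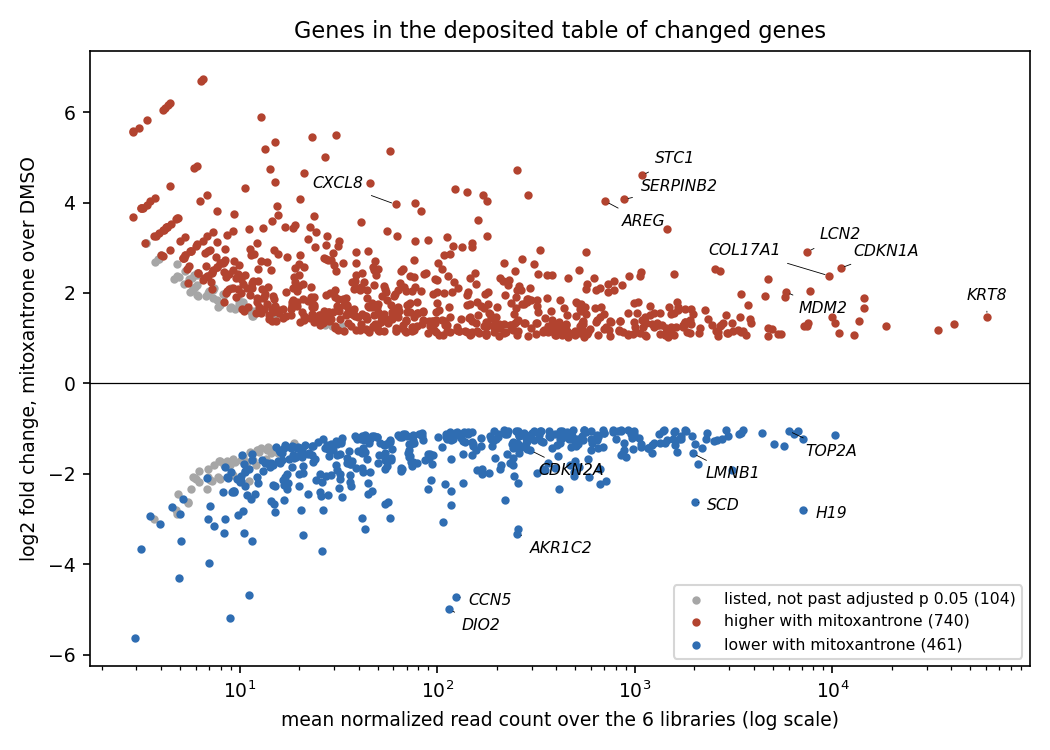
Each point is 1 of the 1305 listed genes, with its mean normalized read count over the 6 libraries (log axis) and its fitted log2 fold change of mitoxantrone over DMSO. Red and blue points are the 740 higher and 461 lower genes past an adjusted p of 0.05, and the 104 grey points lie at low counts. The empty band around 0 follows from the authors' threshold on their own fold changes. Those can be smaller than the fitted ones at low counts, as for H3C12 (log2 fold change -1.15 from the authors, -5.64 fitted).

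The largest rises among protein-coding genes at or above the median expression of the table included several secreted proteins. ANGPTL4, a secreted regulator of lipoprotein lipase, rose from 18.4 ± 1.91 (SD, n = 3) to 487 ± 36.8 (SD, n = 3) normalized reads, a 26.2-fold rise. STC1 rose 24.3-fold, ESM1 (endocan, a secreted proteoglycan) 19.6-fold, CEACAM1 (a cell adhesion receptor) 18.9-fold, CXCL1 (a neutrophil chemokine) 17.9-fold, SERPINB2 (a plasminogen activator inhibitor) 16.7-fold, MMP1 (a collagenase) 16.4-fold and AREG (amphiregulin, a ligand of the EGF receptor) 16.3-fold. TENM4 rose 15.9-fold and SHC4, an adaptor of receptor tyrosine kinases, 14-fold. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave these 10 genes adjusted p-values from 9.5e-10 for ANGPTL4 to 1.5e-07 for TENM4. AREG may share reads with the near-identical gene copy listed as AREGB, which rose 17.9-fold. The CXCL1, CXCL2 and CXCL3 genes resemble one another, so how the reads of all these genes were divided is uncertain.

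The largest falls under the same conditions were DIO2, the deiodinase that activates thyroid hormone, at 223 ± 93.8 (SD, n = 3) with DMSO and 6.93 ± 3.03 (SD, n = 3) with mitoxantrone, and CCN5 (listed as WISP2), a secreted matricellular protein, at 239.8 ± 88.9 (SD, n = 3) and 8.94 ± 2.36 (SD, n = 3). These were 32.1-fold and 26.3-fold lower. The authors' deposited log2 fold changes were smaller than the fitted ones, at -3.40 against -5.00 for DIO2 and -3.98 against -4.72 for CCN5. AKR1C2, an aldo-keto reductase that acts on steroids, was 10-fold lower, the transcription factor gene ATOH8 9.37-fold, RARRES1 8.33-fold, AKR1C1 6.41-fold, SCD (the desaturase that makes monounsaturated fatty acids) 6.15-fold, INSIG1 (a sterol-regulated brake on cholesterol synthesis) 6-fold, the kinase gene MAP2K6 5.25-fold and NRARP, a Notch target, 5.03-fold lower. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave these 10 genes adjusted p-values from 4.3e-08 for AKR1C2 to 2.0e-06 for AKR1C1. AKR1C1, AKR1C2 and AKR1C3 are close in sequence, so the share of each is uncertain.

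Of 46 targets of p53, the transcription factor activated by DNA damage, 26 were listed and all of these rose. Of these, 26 passed over all genes tested and 26 adjusted over the list alone. The count adjusted over the list alone equalled the number of listed members in every list, here and below. The authors had already selected all listed genes as changed on these libraries, which favours that outcome. That count therefore adds no support for any list or gene. With TMM and DESeq2 size factors over the listed genes 20 and 9 of the 26 passed. Those factors centre a set that was selected as changed and mostly higher. They therefore shrink rises and enlarge falls by themselves, here and below. Besides CDKN1A, they included MDM2, the ubiquitin ligase that limits p53 (2304 ± 293 to 9366 ± 614, SD, n = 3 each), and GDF15, a secreted stress hormone (1583 ± 196 to 7902 ± 369.8, SD, n = 3 each). TNFRSF10C, a decoy receptor of the death ligand TRAIL, rose 5.70-fold and FAS, a death receptor, 2.94-fold. Their median log2 fold change was 1.47, at percentile 99.9 of random sets of listed genes matched on expression. The shared direction of the members raises that percentile by itself, whatever the size of the rises. Among the other listed genes 60% were higher, and the difference in direction had an adjusted p of 3.5e-05 (two-sided Fisher's exact test, Benjamini-Hochberg over 17 lists; genes are not independent replicates). Counting only genes with an absolute log2 fold change of at least 2 left out most of the 26, and the p53 targets that remained were all higher. The adjusted p was then 0.26 in the same exact test over 4 testable lists (1.4e-05 to 0.26 over the alternatives).

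Of 64 genes of the senescence-associated secretory phenotype, the inflammatory and matrix-degrading proteins that senescent cells release, 28 were listed. Of these, 25 passed as higher and 2 as lower over all genes tested, and 28 passed adjusted over the list alone. CXCL8 (listed as IL8), a neutrophil chemokine, rose from 7.5 ± 3.57 (SD, n = 3) to 116 ± 21.9 (SD, n = 3), and the cytokine gene IL6 from 19.9 ± 3.89 (SD, n = 3) to 112 ± 24.2 (SD, n = 3). The interleukin 1 genes were more abundant, with IL1A at 752 ± 123 (SD, n = 3) against 4352 ± 323 (SD, n = 3) and IL1B at 329 ± 50.5 (SD, n = 3) against 1810 ± 137 (SD, n = 3). The members that fell were IGFBP3, which binds insulin-like growth factors and was 3.01-fold lower, and the collagenase gene MMP13, with 70 reads over the DMSO libraries and 2 over the mitoxantrone libraries, 29.4-fold lower with a 95% exact counting interval of 7.85 to 248. MMP9, a gelatinase, had a log2 fold change of 1.94 and an adjusted p of 0.085 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; 0.047 without DMSO replicate 2). The list's median log2 fold change was 2.58, at percentile 100 of matched random sets, and its direction differed from that of the other listed genes with an adjusted p of 0.0011 (two-sided Fisher's exact test, Benjamini-Hochberg).

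Genes of the growth factor and MAPK feedback list rose together: 12 of its 28 members were listed, all 12 passed as higher, and 12 passed adjusted over the list alone. AREG and EREG (epiregulin, another EGF receptor ligand) led the list, with EREG at 3.26 ± 2.39 (SD, n = 3) with DMSO and 44.5 ± 14.1 (SD, n = 3) with mitoxantrone. Both are also members of the senescence-associated secretory phenotype list, so the results of these lists are not fully separate. SPRY4, DUSP4 and DUSP5, which encode feedback inhibitors of MAP kinase signalling, were among the others, with log2 fold changes of 2.03, 1.51 and 1.69. With TMM and DESeq2 size factors over the listed genes 10 and 6 of the 12 passed. With the latter, DUSP4 had a log2 fold change of 0.52 and an adjusted p of 0.11 in the edgeR quasi-likelihood test (1.0e-16 to 0.11 over the alternatives). The list's adjusted p was 0.013 (two-sided Fisher's exact test, Benjamini-Hochberg), and its median log2 fold change of 1.57 lay at percentile 98.7 of matched random sets.

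The listed replication and mitosis genes were lower. Of 54 DNA replication genes 10 were listed, and of 75 genes of G2/M and mitosis 31. All of these fell, and 10 and 31 passed adjusted over the list alone. E2F2 and E2F8, transcription factors of the S phase programme, were 4.41-fold and 3.64-fold lower, and MCM5 and MCM6, subunits of the replicative helicase, had log2 fold changes of -1.43 and -1.34. CDC25C, the phosphatase that starts mitosis, fell from 361 ± 38.8 (SD, n = 3) to 107 ± 18.2 (SD, n = 3), and the mitotic kinesin gene KIF15 from 613 ± 129 (SD, n = 3) to 203 ± 21.4 (SD, n = 3). MKI67, the proliferation marker Ki-67, fell 2.51-fold, with an uneven level in the DMSO libraries (9833, 3955 and 7853 normalized reads). Adjusted p-values were 4.6e-04 for replication and 2.4e-12 for G2/M and mitosis (two-sided Fisher's exact test, Benjamini-Hochberg). Median log2 fold changes were -1.36 and -1.16, at percentiles 0.2 and 0.0 of matched random sets. Those percentiles largely repeat the shared direction, since the listed genes were mostly higher. The G2/M and mitosis members ranged only from -1.75 to -1.03, near the authors' fold threshold. Of 42 repair genes of homologous recombination and Fanconi anaemia, RAD54L, RAD51AP1 and RMI2 were listed, all 3 lower, and 3 passed adjusted over the list alone. TOP2A was the 1 listed gene of the 9 in the topoisomerase list and passed adjusted over the list alone.

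Of 16 senescence markers 7 were listed, of which CDKN1A rose and 6 fell, and 7 passed adjusted over the list alone. CDKN2A, the locus of the cell cycle inhibitor p16, fell from 435 ± 67.6 (SD, n = 3) to 156 ± 13.2 (SD, n = 3), and CDKN2C, which encodes the related inhibitor p18, fell 4.67-fold. LMNB1 fell 2.93-fold, and the chromatin protein genes HMGB1 and HMGB2 fell 2.33-fold and 3.78-fold. CDKN1B had a log2 fold change of -1.03. The list mixes genes known to rise in senescence (CDKN2A) with genes known to fall (LMNB1, HMGB1, HMGB2), and its adjusted p for direction was 0.035 (two-sided Fisher's exact test, Benjamini-Hochberg), with a median of -1.48 at percentile 0.1.

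The histone list held 13 listed genes, of which 10 fell and 3 rose, with 13 passing adjusted over the list alone. H2BC21 (listed as HIST2H2BE) rose 2.45-fold and H2BC5 (HIST1H2BD) 2.2-fold, and with TMM factors over the listed genes their adjusted p-values were 0.11 and 0.25 in the edgeR quasi-likelihood test. With TMM or DESeq2 size factors over the listed genes 0 members passed as higher, and without mitoxantrone replicate 3 the lower ones that passed were 6. H3C12 (HIST1H3J) had 20 reads over the DMSO libraries and 0 with mitoxantrone, at least 5.61-fold lower against a floor of 3 reads over the group. That bound leaves out the counting error of the 20 reads, with which the 95% exact limit was 4.15-fold. Its call ended without DMSO replicate 1 or 3 or any 1 mitoxantrone replicate (adjusted p from 0.051 to 0.076, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The list's adjusted p was 0.019 (two-sided Fisher's exact test, Benjamini-Hochberg) and its median log2 fold change was -1.70, also with H3C12 at its bound, at percentile 1.0. That p rose to 0.063 without mitoxantrone replicate 1, 0.11 without mitoxantrone replicate 3, 0.32 for protein-coding genes only and 0.29 for members with an adjusted p under 0.001 (two-sided Fisher's exact test, Benjamini-Hochberg; 0.0016 to 0.32 over the alternatives). Histone genes resemble one another and mostly lack poly(A) tails, and the list's symbol search also took in H1-10, a histone made outside replication, with its antisense gene, and the pseudogene H2AC10P.

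Of the 23 genes of the glutathione, NRF2 and xenobiotic list 8 were listed, all of which fell, and 8 passed adjusted over the list alone. AKR1C2 was followed by CYP1A1, a hydrocarbon-oxidizing enzyme, at 74.2 ± 4.92 (SD, n = 3) with DMSO and 9.33 ± 1.28 (SD, n = 3) with mitoxantrone. SLC7A11, the cystine importer that feeds glutathione synthesis, fell from 3231 ± 617 (SD, n = 3) to 942 ± 108 (SD, n = 3), and ALDH3A1 and GPX2 each had a log2 fold change of -1.90. The adjusted p was 0.0018 (two-sided Fisher's exact test, Benjamini-Hochberg) and the median log2 fold change of -2.07 lay at percentile 0.0 of matched random sets.

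**Figure D2:**
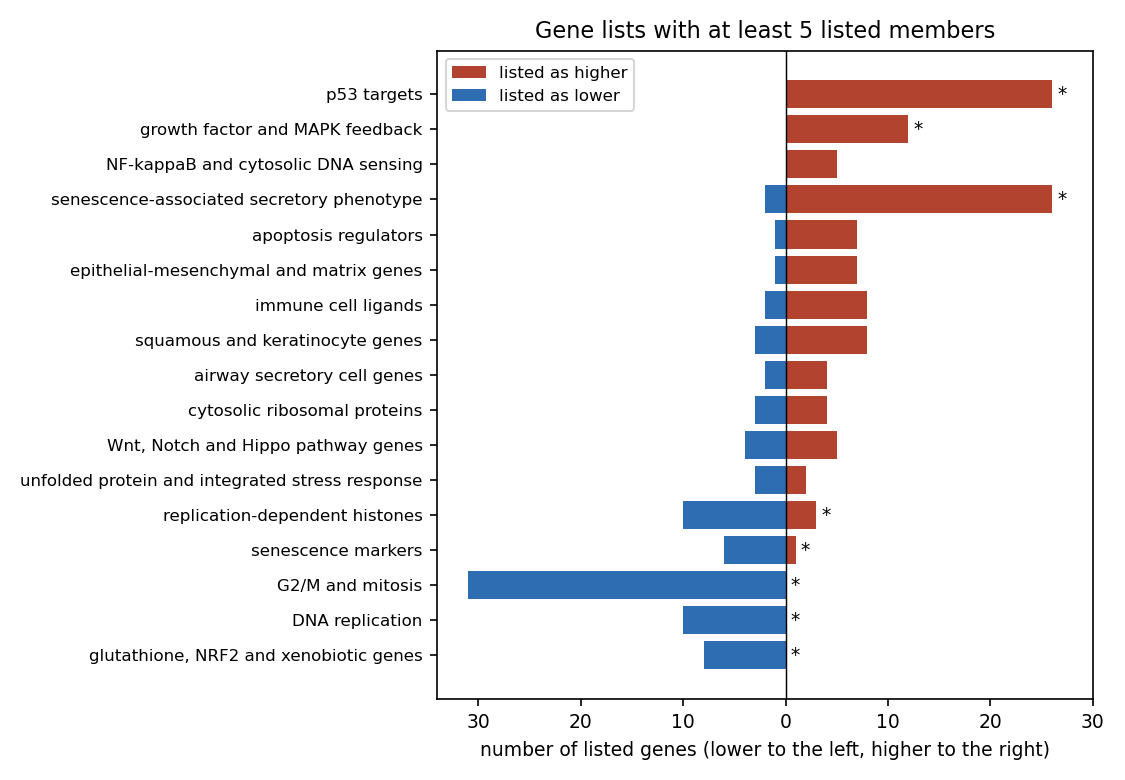
Bars give the number of listed genes higher (red, to the right) and lower (blue, to the left) with mitoxantrone in each of the 17 gene lists with at least 5 listed members. Asterisks mark the 8 lists whose direction differed from that of the other listed genes past an adjusted p of 0.05 in a two-sided Fisher's exact test; the p53 list has 26 higher and 0 lower, and the G2/M list 0 higher and 31 lower.

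Listed ligands that immune cells recognise went mostly up: 10 of 36 were listed, and 8 of the 10 listed members passed as higher and 2 as lower, and 10 passed adjusted over the list alone. PDCD1LG2 and CD274, which encode the PD-1 ligands PD-L2 and PD-L1, rose from 29.5 ± 5.86 (SD, n = 3) to 237 ± 25.6 (SD, n = 3) and from 152 ± 46.8 (SD, n = 3) to 769 ± 56.3 (SD, n = 3). ULBP2, a ligand of the killer cell receptor NKG2D, rose 2.39-fold, and TNFSF10, which encodes the death ligand TRAIL, fell 3.99-fold. As a group these genes did not differ in direction from the other listed genes, of which 60.6% were higher (adjusted p = 0.47, two-sided Fisher's exact test, Benjamini-Hochberg), and their median of 1.48 lay at percentile 94.5. With TMM and DESeq2 size factors over the listed genes 7 and 4 members passed as higher, with 2 lower in each. With the latter, ULBP2 had a log2 fold change of 0.27 and an adjusted p of 1 in the edgeR quasi-likelihood test (2.4e-10 to 1 over the alternatives).

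Epithelial genes moved in both directions. In the squamous and keratinocyte list (11 of 45 listed) 8 of 11 listed members passed as higher and 2 as lower, with 11 adjusted over the list alone (adjusted p = 0.66 for direction, two-sided Fisher's exact test, Benjamini-Hochberg); the median was 2.06 at percentile 99.2. With DESeq2 size factors over the listed genes 5 passed as higher and 3 as lower. The remaining member, the protease gene KLK6, had a log2 fold change of -1.73 and an adjusted p of 0.051 (edgeR quasi-likelihood test, Benjamini-Hochberg; 0.0015 to 0.22 over the alternatives). It passed when scaled by total reads (adjusted p = 0.038, edgeR) and with TMM or DESeq2 size factors over the listed genes. KRT6B, a keratin of activated keratinocytes that shares sequence with KRT6A, rose from 3.95 ± 2.16 (SD, n = 3) to 87.4 ± 3.52 (SD, n = 3), and SERPINB3 and its near copy SERPINB4 fell 2.47-fold and 5.32-fold. In the epithelial-mesenchymal and matrix list (8 of 38 listed) 7 of 8 passed as higher and 0 as lower, with 8 adjusted over the list alone (adjusted p = 0.25, two-sided Fisher's exact test, Benjamini-Hochberg). SNAI1, a transcription factor of epithelial-mesenchymal transition, had a log2 fold change of -1.72 and an adjusted p of 0.071 (edgeR quasi-likelihood test, Benjamini-Hochberg). It passed as lower with TMM or DESeq2 size factors over the listed genes. The list's median was 1.78 at percentile 99.2, with COL17A1, a hemidesmosome collagen, at 3108 ± 357 (SD, n = 3) against 16136 ± 1505 (SD, n = 3), and LAMA3, a laminin chain, rising 4.11-fold. In the airway secretory list (6 of 37 listed) 4 of 6 passed as higher and 2 as lower, with 6 adjusted over the list alone (adjusted p = 1, two-sided Fisher's exact test, Benjamini-Hochberg; median 1.81 at percentile 85.7). With TMM or DESeq2 size factors over the listed genes 2 passed as higher. LCN2, an iron-sequestering antibacterial protein, rose from 1756 ± 316 (SD, n = 3) to 13181 ± 1380 (SD, n = 3). BPIFB1, a family relative of LUNX, had 13.9 ± 6.43 (SD, n = 3) normalized reads with DMSO and 2.56 ± 2.26 (SD, n = 3) with mitoxantrone; its adjusted p was 0.044 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and 0.32 without DMSO replicate 3, 0.063, 0.21 and 0.061 without mitoxantrone replicate 1, 2 and 3, 0.067 among protein-coding genes only and 0.055 with DESeq2 (0.0019 to 0.32 over the alternatives). The other lower member, the transcription factor gene SPDEF, had an adjusted p of 0.0077, and 0.054 without mitoxantrone replicate 3 (edgeR quasi-likelihood test, Benjamini-Hochberg; 7.6e-05 to 0.054 over the alternatives), so that 0 members passed as lower without that library.

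The other lists with at least 5 listed members did not differ in direction from the rest (two-sided Fisher's exact test, Benjamini-Hochberg). The 5 listed genes of the 26 for NF-kappaB and cytosolic DNA sensing all rose, led by TNFAIP3, a feedback inhibitor of NF-kappaB, at 134 ± 35.7 (SD, n = 3) against 999 ± 95 (SD, n = 3) (adjusted p = 0.25, median 1.36 at percentile 85.7, 5 adjusted over the list alone). Of 8 listed apoptosis regulators (31 in the list) 7 rose and BMF, a pro-apoptotic gene, fell 3.86-fold (adjusted p = 0.25, median 1.30 at percentile 75.6, 8 adjusted over the list alone). The survival gene BCL2A1 had 3 reads over the DMSO libraries and 76 with mitoxantrone, 30.1-fold higher with a 95% exact counting interval of 9.93 to 149. With DESeq2 size factors over the listed genes 1 of these NF-kappaB genes and 2 of these apoptosis genes passed as higher. Of 9 listed Wnt, Notch and Hippo genes (28 in the list) 5 rose and 4 fell (adjusted p = 0.84, median 1.06 at percentile 32.4, 9 adjusted over the list alone), with WNT7A, a Wnt ligand, rising 5.34-fold and HEY1, a Notch target, falling 3.51-fold. The same size factors left 3 higher, and 2 were lower without DMSO replicate 1 or mitoxantrone replicate 2. Of 5 listed genes of the unfolded protein and integrated stress response (23 in the list) 2 rose and 3 fell, with 0 higher under DESeq2 size factors over the listed genes (adjusted p = 0.51, median -1.09 at percentile 13.4, 5 adjusted over the list alone), among them SLC7A11 and PHGDH, the first enzyme of serine synthesis, which fell 2.57-fold. The symbol search for ribosomal protein genes found 7 listed genes, 4 higher and 3 lower (adjusted p = 1, median 1.25 at percentile 37.2, 7 adjusted over the list alone). With TMM and DESeq2 size factors over the listed genes 2 and 1 passed as higher. Leaving out DMSO replicate 1 gave 2 higher and 1 lower, and 1 was lower without DMSO replicate 3, without mitoxantrone replicate 1 or 2, and among protein-coding genes only. Of these, 4 were pseudogenes, and the others were RPS27L, a ribosomal protein gene that is also a p53 target, and the kinase genes RPS6KA5 and RPS6KA6. The adjusted p of RPS6KA6, 0.04, was 0.39 and 0.083 without DMSO replicate 1 and 3, 0.067, 0.16 and 0.12 without mitoxantrone replicate 1, 2 and 3, 0.061 among protein-coding genes only, 0.064 with DESeq2, and 9.0e-04 to 0.39 over all alternatives (edgeR quasi-likelihood test, Benjamini-Hochberg).

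Lists with fewer than 5 listed members were not tested for direction. Of 4 listed interferon response genes (62 in the list) 3 passed as higher and 0 as lower (4 adjusted over the list alone), namely TRIM22, OAS2 and IFIT2, with GBP2 at an adjusted p of 0.12 (edgeR quasi-likelihood test, Benjamini-Hochberg; 0.039 without DMSO replicate 2). Of the 30 antigen presentation genes HLA-DRB1 was listed, with a log2 fold change of 1.60 and an adjusted p of 0.019 (1 adjusted over the list alone) that was 0.089 and 0.095 without DMSO replicate 1 and 3 and 0.14 without mitoxantrone replicate 1 (edgeR quasi-likelihood test, Benjamini-Hochberg; 0.0014 to 1 over the alternatives). That list is not complete. The Gene Ontology term for antigen presentation by MHC class II held 11 listed genes, 6 higher and 5 lower. HLA-DRB5, HLA-DOB and HLA-DOA were among them. Of 25 cholesterol synthesis and uptake genes 3 were listed and all 3 fell (3 adjusted over the list alone), among them INSIG1 and MVK, an enzyme of the mevalonate pathway. Of 3 listed hypoxia and glycolysis genes (23 in the list) PFKFB4 passed as higher and CA9 as lower (3 adjusted over the list alone), while CA12 had an adjusted p of 0.057, or 0.017 without mitoxantrone replicate 1 and 0.027 with the length trend removed (edgeR quasi-likelihood test, Benjamini-Hochberg; 0.0041 to 1 over the alternatives). Of 12 efflux transporter genes ABCA1 and ABCC2 were listed and rose with log2 fold changes of 2.06 and 1.58 (2 adjusted over the list alone). CTSS was the 1 listed gene of 33 lysosome genes and rose (1 adjusted over the list alone). Markers of other cell types were few and split in direction: 1 higher and 1 lower passed for each of the leukocyte (ITGAM, CD14), fibroblast (ACTA2, COL1A1) and endothelial (FLT1, CDH5) lists, 0 and 1 (MAP2, with SYP not passing) for neural genes and 1 (RSPH1, with TPPP3 not passing) and 0 for ciliated cells, each with 2 adjusted over the list alone. These lists held 16, 11, 9, 16 and 13 genes, of which 2 each were listed. Of these markers 5 lost the call without some single libraries (edgeR quasi-likelihood test, Benjamini-Hochberg). The adjusted p of ITGAM was 0.061 without mitoxantrone replicate 2, and that of CD14 0.083 without DMSO replicate 3 and 0.062 without mitoxantrone replicate 3. That of FLT1 was 0.053, 0.051, 0.095 and 0.06 without DMSO replicate 1 and 3 and mitoxantrone replicate 1 and 2, and that of RSPH1 0.079, 0.098 and 0.14 without DMSO replicate 1 and 3 and mitoxantrone replicate 3. That of MAP2 was 0.084 and 0.21 without DMSO replicate 1 and 3, and 0.12, 0.053 and 0.053 without mitoxantrone replicate 1, 2 and 3. With DESeq2 size factors over the listed genes the calls of OAS2, IFIT2, HLA-DRB1, PFKFB4, ABCC2, CTSS, ITGAM, ACTA2, FLT1 and RSPH1 ended, with adjusted p-values from 0.27 to 1 in the edgeR quasi-likelihood test. With TMM factors those of OAS2, HLA-DRB1, PFKFB4, CTSS, FLT1 and RSPH1 ended, and GBP2, SYP and TPPP3 passed as lower with either. The list of mitochondrially encoded genes had 0 listed members and 0 adjusted over the list alone.

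**Figure D3:**
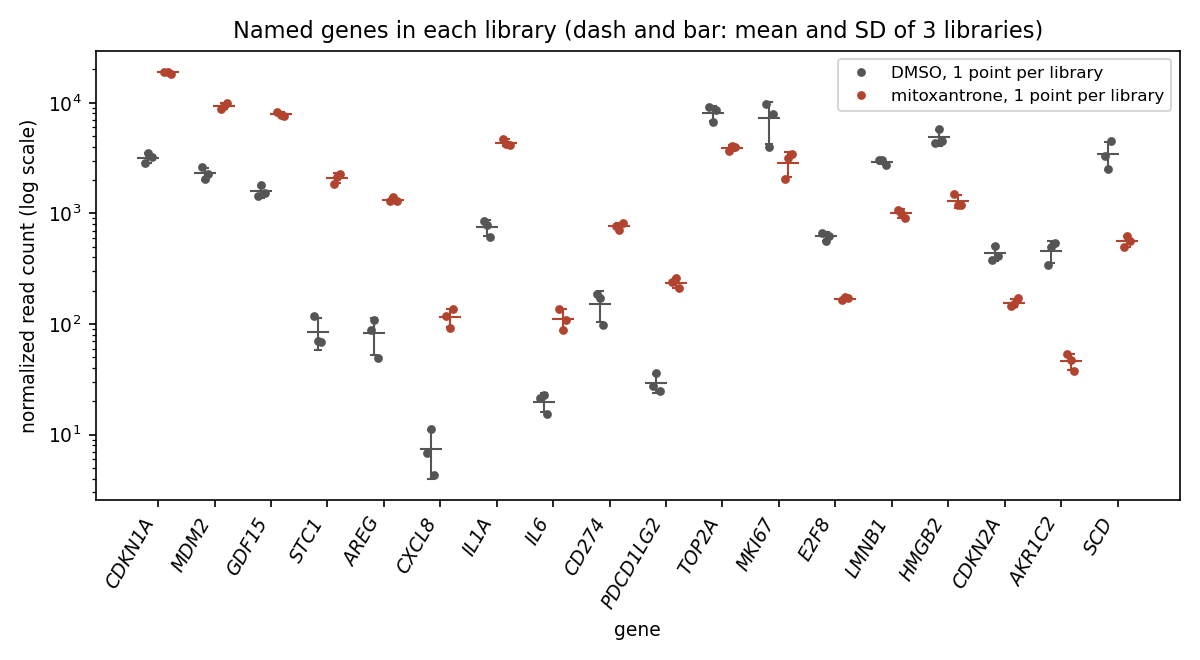
Normalized read counts (log axis) of 18 named genes in each of the 3 DMSO (grey) and 3 mitoxantrone (red) libraries, with dash and bar giving the mean and SD. For each gene shown the 3 libraries of one treatment lie apart from the 3 of the other, with wide scatter in DMSO for CXCL8, from 4.28 to 11.3, and for MKI67, from 3955 to 9833.

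On GRCh38 (GENCODE 29, matched by gene identifier), CDKN1A (ENSG00000124762) lies on chromosome 6 from 36676460 to 36687339 and MDM2 (ENSG00000135679) on chromosome 12 from 68808176 to 68850686. STC1 (ENSG00000159167) lies on chromosome 8 from 23841915 to 23854807 and ANGPTL4 (ENSG00000167772) on chromosome 19 from 8363289 to 8374373. CXCL8 (ENSG00000169429) and AREG (ENSG00000109321) lie on chromosome 4, from 73740506 to 73743716 and from 74445134 to 74455009. CD274 (ENSG00000120217) and PDCD1LG2 (ENSG00000197646) are neighbours on chromosome 9, from 5450503 to 5470566 and from 5510570 to 5571254, and CDKN2A (ENSG00000147889) lies on the same chromosome from 21967753 to 21995301. TOP2A (ENSG00000131747) lies on chromosome 17 from 40388516 to 40417950, LMNB1 (ENSG00000113368) on chromosome 5 from 126776623 to 126837020 and SCD (ENSG00000099194) on chromosome 10 from 100347124 to 100364834. Values are read counts over whole genes, with no separation of exons or isoforms, so the p16 and p14ARF transcripts of CDKN2A were not told apart.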

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

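The alternatives that left out 1 library for the gene lists, scaled by total reads, removed the length trend, adjusted over the listed genes alone or counted list members were chosen only after the data were seen. Against 740 higher and 461 lower genes, an adjusted p under 0.001 left 487 and 301, an absolute log2 fold change of at least 2 left 291 and 102, and a mean of at least the median left 389 and 260 of the 653 genes tested, as fewer genes can pass. TMM and DESeq2 size factors over the listed genes left 398 and 219 higher genes with 512 lower in each, since they centre a set that was mostly higher. The other settings stayed within 1.5 times: 657 and 439 after filterByExpr, 574 and 376 for protein-coding genes, 679 and 427 with the DESeq2 Wald test, 723 and 483 scaled by total reads, 737 and 458 without the length trend, and 793 and 512 adjusted over the listed genes alone. Leaving out 1 library gave 622 to 715 higher and 395 to 463 lower genes. With the label number as a replicate block the counts were 736 and 463. CA12 (higher) and TPPP3 (lower) then passed with adjusted p-values of 0.01 and 0.033 in the edgeR quasi-likelihood test (0.0041 to 1 and 0.0083 to 0.61 over the alternatives). Same-numbered libraries deviated with correlations of -0.44, -0.26 and 0.23. Deviations within a group are tied to one another, so these values cannot show whether the numbers pair the samples. The number of lists past the threshold was 8; it was 7 or 8 under the other settings and 2 of 4 testable lists for members with an absolute log2 fold change of at least 2, where fewer lists can be tested, and 7 to 8 without 1 library. The number of lists with a median outside the central 95% of random sets was 10, and 8 in each alternative. Of the 78 named genes 16 lost the call under some setting, 9 of them only with size factors over the listed genes. The setting on the pseudocount was not run, since it applies to normalized values. In the edgeR test 1 of the 10 splits of the 6 libraries, the real one, called as many as 1201 genes, and the highest of the others called 0 (0 with DESeq2, and at most 3 at an unadjusted p under 0.05); 10 splits are too few for a share under 0.05, and the authors chose these genes for the real grouping, which by itself favours low counts in the others. The 104 listed genes without a call had a median of 7.88 normalized reads. They passed when adjusted over the listed genes alone, but so did every listed gene, so this cannot show what limits them. Low counts and the ranking among listed genes only cannot be told apart as limits here.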

Other observations

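The Gene Ontology, gene class, neighbour, locus length and library tests here were chosen only after the results were seen, except the test of the length trend. Among genes outside the fixed lists, all named here after their values were seen, several rose. PTGS2, the inducible cyclooxygenase, rose from 496 ± 135 (SD, n = 3) to 2667 ± 52.8 (SD, n = 3) normalized reads, and complement C3 from 819 ± 143 (SD, n = 3) to 4563 ± 529 (SD, n = 3). RGS2, a regulator of G protein signalling, rose 10.6-fold and RNASE7, an antimicrobial ribonuclease, 5.59-fold. The simple epithelial keratin gene KRT8 rose from 31927 ± 5353 (SD, n = 3) to 89362 ± 9462 (SD, n = 3) and lost its call only with DESeq2 size factors over the listed genes (adjusted p = 0.36, edgeR quasi-likelihood test). The long non-coding RNA H19, transcribed from an imprinted locus, fell from 12373 ± 1834 (SD, n = 3) to 1790 ± 37.2 (SD, n = 3). ID1 and SMAD6, known targets of BMP signalling, fell 2.22-fold and 3.74-fold, and FADS2, a fatty acid desaturase, fell 2.38-fold beside SCD. Of 78 listed lincRNA genes 57 were higher (73.1%) and of 79 listed antisense genes 43 (54.4%), against 60.2% of 1048 protein-coding genes, and neither difference passed (unadjusted p = 0.03 and 0.34, adjusted p = 0.059 and 0.34 over the 2 classes, two-sided Fisher's exact test, Benjamini-Hochberg).

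Of 125 Gene Ontology process terms with at least 10 listed members, 18 differed in direction from the other annotated listed genes at an adjusted p under 0.05 (two-sided Fisher's exact test, Benjamini-Hochberg), 6 mostly higher and 12 mostly lower, and 15 of 59 did so among genes with a mean of at least the median. Beyond the cell cycle terms, 59 of 92 genes of DNA-templated transcription were lower (35.9% higher against 62.6% of the others, adjusted p = 4.9e-05, two-sided Fisher's exact test), with ATOH8 among the lower ones. Inflammatory response (36 of 43 higher, adjusted p = 0.011, two-sided Fisher's exact test) and extracellular matrix organization (25 of 29 higher, adjusted p = 0.031, two-sided Fisher's exact test) went the other way.

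Of 75 pairs of neighbouring listed genes 10 to 50 kb apart 65 changed in the same direction (86.7%, exact 95% interval 76.8 to 93.4), against 52.3% on average and 64.0% at the upper limit when directions were permuted (one-sided permutation p = 1.0e-04, the smallest that 10000 permutations can give). Pairs 50 to 200 kb apart did in 57.5% of 146 (limit 60.3%), and pairs 200 kb to 1 Mb apart in 61% of 369 (limit 57.5%). Reads counted for both of 2 overlapping genes cannot account for these separated pairs. Pairs with different symbol roots kept 84.7% of 59 (interval 73.0 to 92.8, limit 64.4%). Relatives with short roots, such as IL1A and IL1B, still counted as different, so reads shared between related genes are only partly argued against. Transcription running past a gene's end is only partly argued against. Of 13 divergent pairs 84.6% shared a direction, above the limit of 76.9% (one-sided permutation p = 0.016). The exact 95% interval of 54.6 to 98.1 still takes in that limit, and 13 pairs are few, so the question stays open. For the 39 overlapping pairs (94.9%), reads credited to the wrong gene or to both cannot be told apart from shared change without strand. Shared regulation of neighbouring genes may contribute, as in HOXA5 and HOXA9, which fell 2.31-fold and 2.79-fold, but it was not tested.

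DMSO replicate 2 and mitoxantrone replicate 1 deviated from their groups in the same genes, with a correlation of 0.59 across 707 genes, the highest of the 9 pairs between the groups (genes are not independent replicates). Total reads are argued against as the whole cause. Mitoxantrone replicate 3 had 1.005 times the reads of replicate 1, yet the difference of replicate 1 from 3 followed the deviations of DMSO replicate 2 at 0.59 (0.17 for replicate 2 from 3). That difference contains replicate 1 itself, so it partly restates the pattern. DMSO replicate 2 and mitoxantrone replicate 1 each had the lowest size factor of their group (0.971 and 0.884). A wrong size factor shifts all genes of a library nearly alike, and a correlation across genes leaves such a shift out. A single scaling factor per library therefore cannot account for the correlation of 0.59. Fewer dividing cells cannot be told apart from other differences, since the 41 replication and mitosis genes went both ways, with median deviations of -0.03 log2 (quartiles -0.23 to 0.13) and 0.05 (-0.08 to 0.12) in these libraries (0.13 and 0.08 for the 16 shorter than 3595 bases against -0.17 and -0.03 for the others). In both libraries longer genes read lower (Spearman correlation of deviation with length -0.54 and -0.44), and MKI67 read lowest of its group in DMSO replicate 2. A length trend, as from RNA or fragment length, may account for part of it, but removing the trend left a correlation of 0.48, between the bounds of 0.3 and 0.5 set before, so it cannot be told apart from other differences between libraries.

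A hypothesis that a poisoned topoisomerase lowers genes with long loci more often was tested on the listed protein-coding genes. Of the 262 genes with the longest genomic spans (at least 72.4 kb) 36.6% were lower, against 40.8% of the other 786, a difference of -4.20 points (95% interval -11.0 to 2.6; p = 0.24, two-sided Fisher's exact test). An excess of 10 points or more among the longest listed genes lies outside that interval, and smaller falls, left out by the authors' fold threshold, were not analysed here.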
